A study of Mus musculus with 5 samples.

How the data were processed

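Genomic DNA of sorted common myeloid progenitors from 3 pools of G0 and 2 pools of G5 mice was profiled by reduced representation bisulfite sequencing. Per the labels, 29 to 38 M reads were made for a sample and about 63% aligned. Per the submitters' processing notes, reads were aligned to mm10 with Bowtie through Bismark 0.7.11, and methylation of both kinds of mice was compared with methylKit. The series' design text names Fisher's exact test for that comparison, a promoter window from 1 kb upstream to 500 bp downstream of RefSeq start sites, and exons, introns and CpG islands from the UCSC mm10 annotation. Versions of Bowtie and methylKit and the minimum coverage are not given in the sources used here.

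The authors deposited 2 tables, of positions higher and of positions lower in G5. Each row holds a p-value and a q-value from the authors' test, a methylation difference in percentage points, annotation flags, the nearest start site and its gene, and the percent methylation of each of the 5 samples, per the file headers. In the files every q-value was under 0.01 and every absolute difference over 10 points. The authors' difference and the plain difference of group means had the same sign at every position and differed by a median of 0.570 points. Fisher's test on pooled reads, if so run, does not count the spread between pools, so the authors' q-values describe these libraries more than the groups. The tables list only positions that passed, so no enrichment against all measured CpGs can be had. They give no coverage, so the depth behind a level is unknown. The test of methylated read counts with a quasi-binomial model, set before the data were examined for the case that read counts were given, was not run, nor was the coverage minimum of 20 reads.

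Positions were checked against GRCm38, the assembly of mm10. Of 4688 positions 2332 lay on the cytosine of a CpG and 2356 on the base before it, so all were placed on 4636 distinct CpGs. This was read as the cytosines of both strands with positions counted from 0, since the tables name no strand, and positions are printed as the files give them. For 52 CpGs both starts were listed, 0 of them in opposite directions and 0 with identical percents in all 5 samples, so they are separate measurements. No column belonged to a sample outside the series. Column names carry the sample titles, and groups come from those titles. The pools are labelled as separate pools of mice. That G5 mice are homozygous for TERT-ER comes from the genotype labels. The series title speaks of G4/G5, while every sample of that group is labelled G5, and G5 is written here.

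Group means and SDs were taken over samples, after averaging the listed positions of a gene within each sample. Neighbouring CpGs of 1 fragment are not independent, so tests between the lists used clusters, in which each position lies within 1 kb of the next on the same chromosome and list. Shares of clusters in promoters, CpG islands, gene bodies and the distal 5 Mb were compared with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 4 features, and likewise over 21 chromosomes and 13 gene lists. The size of differences was compared by a permutation test with 100000 resamples. Intervals of shares are 95% Wilson intervals and cover counting error over clusters only. The p-values of tests over clusters likewise take clusters as the unit and do not measure the spread between pools. The shares were not recomputed with a pool left out. The interaction of island and X chromosome was tested with Zelen's exact test and a logistic model over clusters, both chosen after seeing the data. Limma 3.58.1 (R 4.3.3) was run on the percent values of the listed positions, also chosen after seeing the data. On simulated percents for 4688 positions of this comparison, limma recovered 1.49% of shifts of 10 points, 52.2% of 20 points and 69.7% of 30 points, and called 6 of 4488 unchanged positions. The simulation gave both groups the spread of the G0 pools and left most positions unchanged. The listed positions had all been selected for a difference, so these rates need not hold for the calls made here. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9. Groups of 3 and 2 samples were too small for an outlier test.

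Named genes followed a rule set before the data were examined. It took, per direction, the 6 genes with the most positions, the 6 with the largest difference at a promoter position, and from each gene list the member with the most positions, and then the 3 genes with the most positions among those listed in both directions. This gave 44 genes. Genes at positions past 60 points, and lists of members without values, are outside the rule. Some list members are not reported here by name.

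Alternatives set beforehand were a q-value under 0.001, differences of at least 40 points, autosomes only, single positions as the unit, a cluster gap of 10 kb, a promoter window of 2 kb on either side, promoters from the RefSeq annotation of GRCm38, stricter islands (500 bp, GC over 55%, observed to expected CpG over 0.65), 2 and 10 Mb from chromosome ends, 2 positions per gene, and genes as the unit. Those added after seeing the data were positions without overlap of the groups, mean levels of 20 to 80%, positions within 10 kb of a start site, the removal of distal chromosome 4, clusters as the unit of the test of isolated positions on chromosome 4, and limma with and without the replicate number as a block, and the removal of each sample in turn. The removal of distal chromosome 4 was also applied to differences of at least 40 points. With genes as the unit, genes listed in both directions were left out.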

Results

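Reduced representation bisulfite sequencing reads the methylation of cytosines in CpG-rich parts of the genome after a restriction digest. It was applied here to common myeloid progenitors (CMP), the bone marrow cells from which granulocytes, monocytes, red cells and platelets arise. The cells were sorted from mice that carry the TERT-ER allele, a fusion of telomerase reverse transcriptase to the oestrogen receptor ligand-binding domain that leaves telomerase inactive without its ligand. There were 3 pools of G0 mice, which are heterozygous for the allele and are called normal in the sample descriptions. The other 2 pools came from G5 mice, which are homozygous for it and described as having short telomeres. The comparison asks where DNA methylation differs between progenitors of the 2 kinds. Each pool held 14000 to 30000 cells and gave at least 45 ng of DNA, and sequencing gave 29 to 38 M reads for a sample, of which about 63% aligned. The deposited tables list positions that passed the authors' test, with the percent methylation of each of the 5 samples. The read depth behind a single percent value is unknown, so no counting interval is given for any level.

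The locus that carries the engineered allele was examined first. In Tert, which encodes the catalytic subunit of telomerase, all 8 listed positions were higher in G5. They cover 7 CpGs at chromosome 13, 73627083 to 73627152 (mm10), from 84 to 153 bp downstream of the authors' RefSeq start site, inside the promoter window, a CpG island and the coding part of exon 1. Averaged over the 8 positions, methylation was 42.7% ± 8.61 (SD, n = 3) in G0 and 87.2% ± 0.236 (SD, n = 2) in G5, a difference of 44.6 points. The single pools stood at 52.1%, 40.8% and 35.2% in G0 and at 87.4% and 87.1% in G5. The groups did not overlap at any of the 8 positions, and all 8 passed limma's moderated test over the listed positions, with a smallest adjusted p of 0.0412. The exon runs from 73626916 to 73627248 with its start codon at 73627030, and the stretch from 73627084 to 73627153 reads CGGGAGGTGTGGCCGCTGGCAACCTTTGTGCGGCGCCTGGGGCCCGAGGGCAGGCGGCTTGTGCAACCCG on the plus strand. All 7 CpGs of that 70 bp stretch were listed. The exon bounds are those of the GENCODE annotation, which begins the exon upstream of the RefSeq start site used for the distances.

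**Figure D1:**
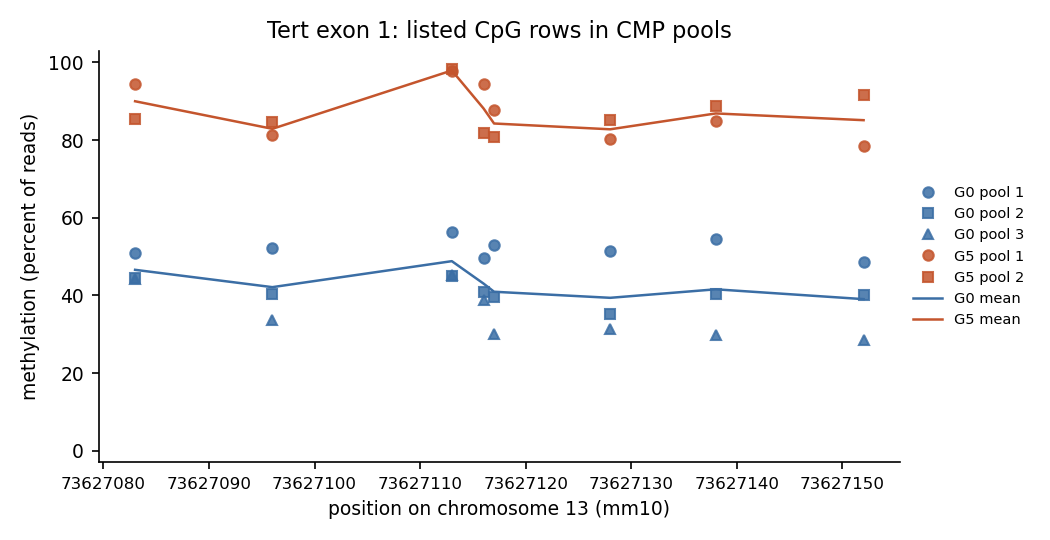
Methylation in percent of reads (vertical axis) at the 8 listed Tert positions along chromosome 13 (horizontal axis, mm10), with a point per pool and lines through the group means of 3 G0 and 2 G5 pools. The G5 means run from 82.8% to 97.9% and the G0 means from 39.0% to 48.8%, and no G0 point reaches a G5 point of the same position.

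Across the genome, methylation moved in both directions. The lists held 2618 positions with higher methylation in G5 and 2070 with lower methylation, so 55.8% were higher. At the higher positions the median level of a sample was 39.0% ± 0.128 (SD, n = 3) in G0 and 62.5% ± 3.04 (SD, n = 2) in G5. At the lower positions it was 58.9% ± 1.27 (SD, n = 3) in G0 and 34.5% ± 1.31 (SD, n = 2) in G5. Per the authors' deposited table, the median absolute difference was 16.3 points for higher and 16.5 points for lower positions. Taken over clusters of neighbouring positions, the median sizes were 15.6 and 16.0 points, a difference of -0.411 points that did not pass (permutation test, two-sided, p = 0.0634). Without the distal part of chromosome 4 it was -0.454 points (permutation test, p = 0.0377). Among differences of at least 40 points the sign turned, to 16.6 points (permutation test, p = 0.00278), which rested on distal chromosome 4, since without it the difference was -0.770 points (permutation test, p = 0.537). Pools of one kind resembled each other more than pools of the other kind. Across the listed positions, which are not independent and were chosen for a group difference, Pearson's r was 0.953 to 0.960 between G0 pools, 0.885 between the G5 pools and 0.775 to 0.802 across groups.

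The levels of all G5 pools lay beyond those of all G0 pools, in the listed direction, at 2276 of the 2618 higher positions (86.9%) and at 1737 of the 2070 lower positions (83.9%), where chance gives 10% of unselected positions in a given direction. In limma's test across the 5 samples, with Benjamini-Hochberg adjustment over the listed positions, 868 higher positions (33.2%) and 683 lower positions (33.0%) passed an adjusted p of 0.05. These positions had been selected on the same samples, so the counts are no independent evidence of a difference. The limma counts changed with the pool left out. Without G0 pool 1 or G0 pool 3 there were 0 calls in either direction, with 1255 and 1083 higher and 930 and 883 lower positions at an unadjusted p under 0.05. Without G0 pool 2 there were 9 higher and 0 lower calls, with 1128 and 917 positions at an unadjusted p under 0.05. Without G5 pool 1 there were 844 higher and 708 lower calls, of which 453 and 348 were among the calls of all pools, and without G5 pool 2 there were 782 and 609, of which 406 and 343 were. A permutation of the labels over 3 and 2 samples has 10 splits and cannot give a p below 0.1 for a single position.

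The positions lay nearest to 2797 genes, of which 1295 had only higher positions, 1188 only lower positions and 314 both. A gene name here is the nearest start site at any distance. The median distance was 7744 bp, 54.3% of positions were within 10 kb, and 516 were over 100 kb away.

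Among genes with the most higher positions, Kcns1, a modifier subunit of voltage-gated potassium channels, led with 22 positions at chromosome 2, 164167794 to 164168820. Of these 21 were exonic, 21 lay in a CpG island, and the mean level was 16.4% ± 2.04 (SD, n = 3) in G0 and 35.8% ± 3.86 (SD, n = 2) in G5. The 18 positions assigned to Tpp1, a lysosomal peptidase gene, were in an exonic island at -10122 to -10563 bp from its start site (chromosome 7, 105762328 to 105762769) and stood at 36.6% ± 0.331 (SD, n = 3) in G0 and 60.2% ± 10.2 (SD, n = 2) in G5. The 17 positions assigned to Lrg1, which encodes a secreted leucine-rich glycoprotein, were in an exonic island at -2036 to -2836 bp from its start site. They lay upstream of it, so the exon is not downstream of that start. By the authors' test they rose from 67.5% ± 6.67 (SD, n = 3) to 84.1% ± 0.0341 (SD, n = 2), and 3 of them passed limma. The forkhead factor gene Foxf1 had 15 positions between 735 and 5325 bp downstream of its start site, 9 in an island, at 21% ± 1.29 (SD, n = 3) in G0 and 39.9% ± 8.69 (SD, n = 2) in G5. Neurl1b, a ubiquitin ligase gene of the Notch pathway, had 13 exonic island positions at 78.9% ± 12.4 (SD, n = 3) and 95.5% ± 0.0384 (SD, n = 2). In the promoter of Scx, which encodes the tendon transcription factor scleraxis, 13 positions at chromosome 15, 76457493 to 76457796, went from 10.7% ± 1.09 (SD, n = 3) to 26.6% ± 0.341 (SD, n = 2), and the groups did not overlap at any of the 13. Without G0 pool 2 the Neurl1b difference was 9.42 points, against 16.6 with it. Limma passed 8 of 22 positions in Kcns1, 7 of 18 in Tpp1, 5 of 15 in Foxf1, 1 of 13 in Neurl1b and 7 of 13 in Scx.

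The largest promoter differences toward higher methylation, after Tert, included 3 genes of the X chromosome. Fmr1, whose product binds RNA and whose human counterpart is silenced in fragile X syndrome, had 1 promoter island position at 68679217, at 22.7% ± 9.74 (SD, n = 3) in G0 and 60.1% ± 12.9 (SD, n = 2) in G5. The cation channel gene Trpc5 stood at 32.0% ± 3.24 (SD, n = 3) and 59.8% ± 13.5 (SD, n = 2) over 3 promoter positions. The mitochondrial carrier gene Slc25a14 stood at 27.3% ± 8.34 (SD, n = 3) and 58.9% ± 0.949 (SD, n = 2) over 2. On autosomes, the homeobox gene Gbx2 had 7 positions at -528 to -4548 bp from its start site, on chromosome 1, 89931703 to 89935723, with 47.4% ± 7.10 (SD, n = 3) in G0 and 73.3% ± 4.76 (SD, n = 2) in G5. Noxa1, an activator of NADPH oxidase, had 2 promoter positions at 35.4% ± 5.39 (SD, n = 3) and 61.2% ± 19.4 (SD, n = 2), of which 0 passed limma. Fmr1 and Gbx2 also had positions in the other direction. Another promoter island position of Fmr1, at 68679330, stood at 36.9% ± 7.17 (SD, n = 3) and 8.49% ± 12 (SD, n = 2). Inside Gbx2, 4 exonic island positions 2183 to 2237 bp downstream of the start site stood at 63.0% ± 1.03 (SD, n = 3) and 36.9% ± 6.59 (SD, n = 2), and 3 of them passed limma. Without G5 pool 1 the Trpc5 difference was 18.2 points, and without G5 pool 2 the Noxa1 difference was 12.1 points.

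Among promoter positions, the largest differences toward lower methylation included the island of Gm7120 on chromosome 13, where 4 positions between 119489072 and 119489107 stood at 65.2% ± 14.0 (SD, n = 3) in G0 and 17.7% ± 20.3 (SD, n = 2) in G5. All 4 passed limma, and the G5 pools were at 32.1% and 3.32%. The neighbouring transcript 3110070M22Rik had the most lower positions, 16 in its promoter island at 119488333 to 119488531, with 72.6% ± 12.4 (SD, n = 3) in G0 and 40.1% ± 52.3 (SD, n = 2) in G5. That difference came from G5 pool 2 alone, at 3.14% against 77.1% in G5 pool 1. None of the 16 positions separated the groups, and without G5 pool 2 the mean was 4.46 points higher in G5. Hoxa5, a homeobox gene of axial patterning, had 13 promoter island positions at chromosome 6, 52203956 to 52204173, at 63.7% ± 6.73 (SD, n = 3) in G0 and 39.4% ± 19.6 (SD, n = 2) in G5. The groups were apart at 8 of the 13, and 4 passed limma. Without G5 pool 1 the mean difference was -10.4 points.

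Further lower positions lay in gene bodies. The kinase gene Lmtk3 had 10 positions, 9 of them exonic, at 80.4% ± 3.36 (SD, n = 3) in G0 and 59.8% ± 18.3 (SD, n = 2) in G5. The groups were apart at 5 of these 10, and 3 passed limma. Kcnn4, a calcium-activated potassium channel of blood cells, had 9 positions at 58.1% ± 7.77 (SD, n = 3) and 34.9% ± 7.58 (SD, n = 2), 3 of them past limma. The 9 intronic positions assigned to the SNARE gene Ykt6 lay at least 50828 bp from its start site and stood at 31.5% ± 15.9 (SD, n = 3) and 4.39% ± 2.23 (SD, n = 2). Of these 1 passed limma. Among promoters, the vomeronasal receptor gene Vmn2r29 had 6 island positions at 41.7% ± 9.04 (SD, n = 3) and 10.9% ± 4.12 (SD, n = 2), all 6 past limma. It also had 4 higher promoter positions, at 52.6% ± 1.96 (SD, n = 3) and 76.7% ± 12.5 (SD, n = 2), of which 1 passed limma. Assigned to Ykt6 was 1 higher intronic position, 31777 bp from its start site, which did not pass. It stood at 87.7% ± 2.83 (SD, n = 3) and 98.5% ± 2.19 (SD, n = 2). The non-coding gene 5430440P10Rik had 1 position at 64.0% ± 9.0 (SD, n = 3) and 26.2% ± 12.5 (SD, n = 2). The single promoter positions of Ffar1, a fatty acid receptor, and Syce2, a synaptonemal complex gene, did not separate the groups. Ffar1 stood at 83.3% ± 16.2 (SD, n = 3) and 48.5% ± 24.4 (SD, n = 2), and Syce2 at 58.8% ± 19.1 (SD, n = 3) and 23.8% ± 20.2 (SD, n = 2). The differences moved with single pools, to 15.3 points at the higher Vmn2r29 positions without G5 pool 2, to -7.70 points in Lmtk3 without G5 pool 2, to -18.1 in Ykt6 without G0 pool 2, and to -17.5 in Ffar1 and -20.7 in Syce2 without G5 pool 1.

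Some genes were assigned listed positions in opposite directions. The assignment is by nearest start site, so these positions need not lie within the gene named. Assigned to Arhgap9, a GTPase activating protein of blood cells, were 5 higher exonic island positions 2840 to 3228 bp from its start site. They stood at 49.7% ± 3.29 (SD, n = 3) in G0 and 64.2% ± 5.42 (SD, n = 2) in G5. The 9 lower positions assigned to Arhgap9 lay 8665 to 8925 bp from that start site. Their level was 56.4% ± 2.73 (SD, n = 3) in G0 and 38.6% ± 18.9 (SD, n = 2) in G5. Bcor, the X-linked gene of a transcriptional corepressor mutated in myeloid disease, had 12 lower positions spread up to 340858 bp from a start site, at 38.0% ± 2.28 (SD, n = 3) and 23.9% ± 1.19 (SD, n = 2). It also had 1 higher promoter position, at 1.74% ± 1.63 (SD, n = 3) and 14.3% ± 11 (SD, n = 2). The non-coding gene 1700030C10Rik had 6 positions in each direction, up to 1111323 bp from its start site. The higher ones stood at 62.3% ± 11 (SD, n = 3) and 82.0% ± 5.66 (SD, n = 2), and the lower ones at 53.8% ± 3.57 (SD, n = 3) and 36.7% ± 6.60 (SD, n = 2). Limma passed 1 of 5 higher and 2 of 9 lower Arhgap9 positions, 0 of 1 and 3 of 12 in Bcor, and 0 of 6 and 3 of 6 in 1700030C10Rik. Without G5 pool 2 the difference was -4.39 points at the lower Arhgap9 positions and 4.82 points at the higher Bcor position.

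Positions with higher methylation lay more often in CpG islands than positions with lower methylation. Over clusters of positions no more than 1 kb apart, 650 of 1816 higher clusters (35.8%, 95% Wilson interval 33.6 to 38.0) touched an island, against 415 of 1651 lower clusters (25.1%, 23.1 to 27.3). The difference was 10.7 points with an odds ratio of 1.66 (Fisher's exact test, two-sided, adjusted over 4 features, p = 4.38e-11). Restricted to positions without overlap of the groups it was 6.20 points (adjusted p = 0.000953). At the island positions that were higher, the median level of a sample was 15.8% ± 0.416 (SD, n = 3) in G0 and 35.5% ± 1.19 (SD, n = 2) in G5. At the lower island positions it was 22.6% ± 0.821 (SD, n = 3) and 6.21% ± 0.173 (SD, n = 2). Gene bodies held 1150 higher clusters (63.3%) and 958 lower clusters (58.0%), a difference of 5.30 points (adjusted p = 0.00305). Restricted to positions without overlap of the groups, the gene body difference was 3.91 points (adjusted p = 0.0566), and restricted to mean levels of 20 to 80% it was 3.65 points (adjusted p = 0.321). Promoters held 536 higher clusters (29.5%) and 429 lower clusters (26.0%), a difference of 3.53 points (adjusted p = 0.0276). That promoter difference turned to -0.496 points at a q-value under 0.001 and to -0.580 points at positions without overlap. The tests compare both lists with each other, since the CpGs that were tested and not listed are not known. They take clusters as the unit, so their p-values do not measure the spread between pools.

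**Figure D2:**
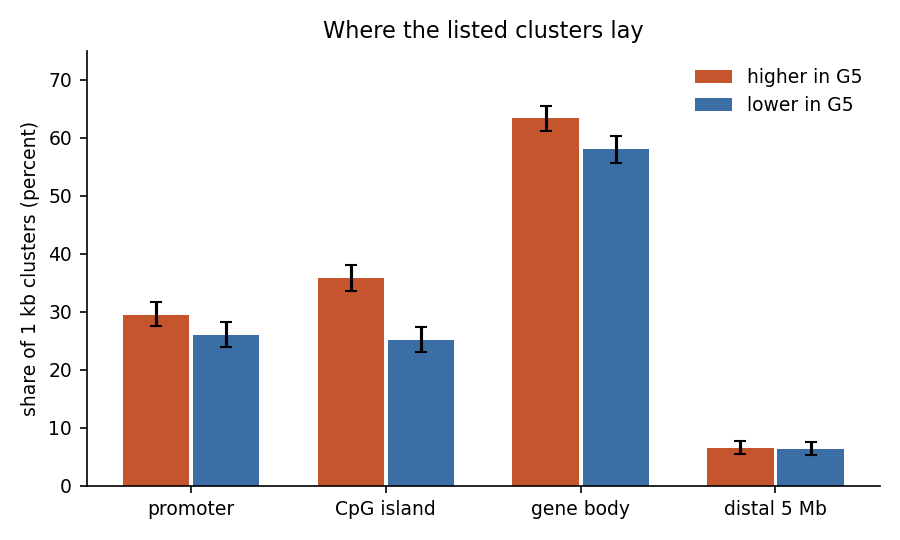
Share of the 1816 higher and 1651 lower clusters (vertical axis, percent) that touched a promoter, a CpG island, a gene body or the distal 5 Mb of a chromosome, with 95% Wilson intervals as error bars. CpG islands show the widest gap, 35.8% against 25.1%, and the distal 5 Mb the narrowest, 6.55% against 6.30%.

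Because the G5 mice had short telomeres by their labels, the ends of chromosomes were examined separately. Of the higher clusters 119 (6.55%) and of the lower clusters 104 (6.30%) lay within 5 Mb of the distal end of their chromosome, a difference of 0.254 points that did not pass the test (Fisher's exact test, adjusted p = 0.782). At 40 points or more it was 33.3 points, 11 of 22 against 2 of 12 clusters (Fisher's exact test, adjusted p = 0.300). Most of those higher clusters lay on distal chromosome 4, and without it the counts were 1 of 9 and 2 of 12. Of 21 chromosomes, X alone had a share that passed the test between the directions. It held 126 higher clusters (6.94%) and 173 lower clusters (10.5%), a difference of -3.54 points (Fisher's exact test, adjusted over chromosomes, p = 0.00453). Among differences of at least 40 points that sign turned, to 4.55 points. X-linked promoter islands moved both ways. There 144 positions of 86 genes were lower, with sample medians of 34.7% ± 1.41 (SD, n = 3) in G0 and 14.1% ± 1.13 (SD, n = 2) in G5, and 78 positions of 50 genes were higher, with 27.4% ± 0.860 (SD, n = 3) and 48.0% ± 2.79 (SD, n = 2). The excess of islands among higher clusters was a feature of the other chromosomes, where 34.3% of higher and 21% of lower clusters touched an island (Fisher's exact test, p = 5.09e-17). On X the shares were 55.6% and 60.7% (Fisher's exact test, p = 0.406). The difference between X and the rest was itself past the threshold (exact test of equal odds ratios, 0.810 and 1.97, p = 0.000532). A logistic model over 3467 clusters put the interaction at -0.889 ± 0.251 (SE) in log odds.

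**Figure D3:**
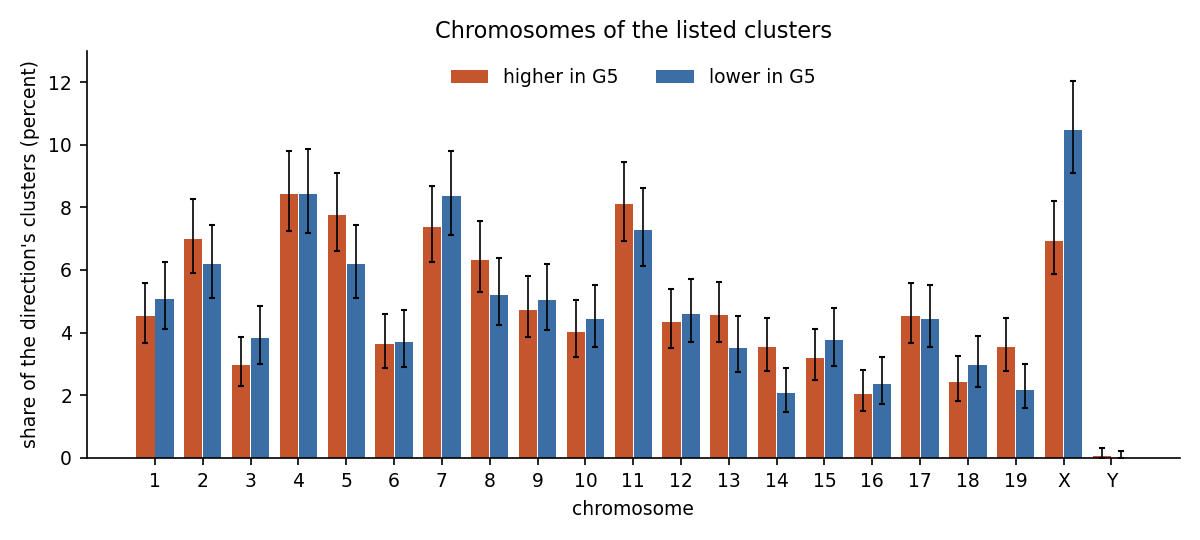
Share of all higher and of all lower clusters found on each chromosome (vertical axis, percent; horizontal axis, chromosome), with 95% Wilson intervals as error bars. On X the lower clusters make up 10.5% and the higher clusters 6.94%.

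The positions with the largest differences were confined, above 60 points, to 1 region. All 11 lay on distal chromosome 4 between 150157765 and 155906185 and all were higher in G5, by 66.4 to 96.5 points per the authors' deposited table. They were assigned to Slc2a7, Errfi1, Vamp3, Plekhg5, Tnfrsf25, Kcnab2, Nphp4, BC039966, Megf6, Arhgef16 and Acap3, genes named after their values were seen. The median of the 11 was 97.6% and 96.9% in the G5 pools and 0% in G0 pools 1 and 3, and 40.5% in G0 pool 2. G0 pool 2 ranged from 12.5% to 54.7% over these positions. At the Acap3 position G0 pools 1 and 3 stood at 9.52% and 34.4%, and at the Plekhg5 position G5 pool 2 stood at 75%. The interval held 77 listed positions, of which 43 were higher.

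**Figure D4:**
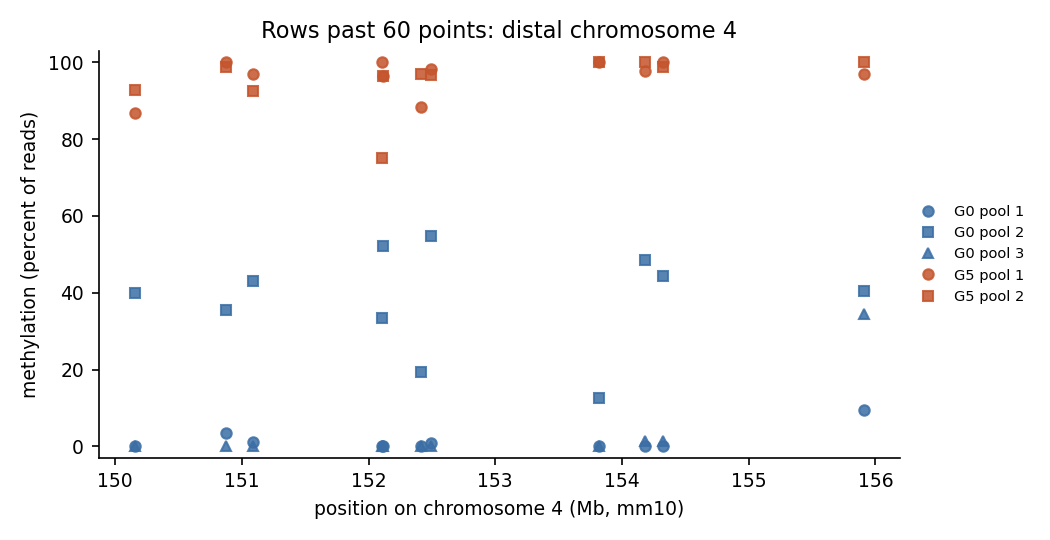
Methylation in percent of reads (vertical axis) of each pool at the 11 positions past 60 points, by position on chromosome 4 in Mb (horizontal axis, mm10), with a point per pool. Both G5 pools lie at 75% or above, G0 pools 1 and 3 lie at 0% for most positions, and G0 pool 2 lies between them.

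Gene groups fixed before the data were examined held 688 genes, of which 198 had a listed position, and 2 of the 13 groups differed in direction from all other clusters. Homeobox and other developmental transcription factors, which pattern the embryo, were the larger. Of 161 genes 94 had a position, 48 only higher ones, 26 only lower ones and 20 both. Their clusters were higher in 97 and lower in 52 cases (65.1% higher, against 51.8% of other clusters; Fisher's exact test, adjusted over 13 groups, p = 0.00925). Clusters that touched a CpG island were themselves more often higher, and the group was not compared with other island clusters. Higher members besides Foxf1 included Pax2, Sox2 and Tbx5, and lower members besides Hoxa5 included Otx2 and Hoxd11. By limma 50 of 157 higher and 24 of 73 lower positions of the group passed, and 49 and 22 when adjusted over the list alone. The excess of 13.3 points over other clusters did not pass over positions without overlap (10.2 points, adjusted p = 0.0816), over levels of 20 to 80% (16.8 points, adjusted p = 0.197), within 10 kb of start sites (12.4 points, adjusted p = 0.218) or with genes as the unit (13.1 points, adjusted p = 0.213). The last of these also left out the 20 genes with positions in both directions.

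Genes recurrently mutated in myelodysplastic syndrome, a disease of ineffective blood formation, formed the other group. Of 36 genes 8 had a position, and their clusters were higher in 3 and lower in 17 cases (15% higher, against 52.6%; Fisher's exact test, adjusted p = 0.00925). Bcorl1, Cbl, Dnmt3a, Gata2 and Stag2 had only lower positions, Cebpa and Tet2 only higher ones, and Bcor both. Of the 22 lower positions 16 were on the X chromosome, in Bcor, Bcorl1 and Stag2, and on autosomes alone the counts were 2 and 5 (-24.8 points, adjusted p = 0.853). The difference of -37.6 points over all clusters also did not pass at a q-value under 0.001 (-44.0 points, adjusted p = 0.0878), over levels of 20 to 80% (-38.7 points, adjusted p = 0.371), within 10 kb of start sites (-32.9 points, adjusted p = 0.380) or with genes as the unit (-23.6 points, adjusted p = 1.0). The last of these also left out Bcor, which had positions in both directions and 12 of the 22 lower ones. By limma 7 of the 22 lower and 0 of the 3 higher positions passed, and 11 and 1 when adjusted over the list alone. Dnmt3a, the de novo DNA methyltransferase, had 2 lower positions at 54.3% ± 0.491 (SD, n = 3) in G0 and 44.4% ± 8.77 (SD, n = 2) in G5. Cebpa, the factor that commits progenitors to the granulocyte lineage, had 1 higher position 9747 bp from its start site, at 34.9% ± 5.34 (SD, n = 3) and 60.8% ± 18.1 (SD, n = 2). Neither gene had a position past limma, and the difference was -3.76 points in Dnmt3a without G5 pool 2 and 13.2 points in Cebpa without G5 pool 1.

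The blood lineage groups did not pass. Lymphoid genes, markers of cells outside the CMP gate, were higher in 10 clusters and lower in 1 (90.9% higher; Fisher's exact test, adjusted p = 0.0545). Members with only higher positions included Cd37, Cd3e, Dntt, Eomes, Pax5 and Tbx21, and Bcl11b had both. By limma 5 of 12 higher and 0 of 2 lower lymphoid positions passed, and 10 and 1 when adjusted over the list alone. Dntt, the terminal transferase of early lymphocytes, had 3 intronic positions at 32.6% ± 6.82 (SD, n = 3) in G0 and 53.7% ± 7.57 (SD, n = 2) in G5, all 3 past limma. The lower Bcl11b positions stood at 68.1% ± 6.66 (SD, n = 3) and 50.8% ± 1.49 (SD, n = 2), and its 3 higher ones at 55.7% ± 0.244 (SD, n = 3) and 70.4% ± 3.40 (SD, n = 2). Haematopoietic transcription factors were higher in 7 and lower in 12 clusters (adjusted p = 0.809). Cebpa, Gfi1, Hlf, Irf8 and Mycn had only higher positions, and Cebpb, Gata2, Klf4, Prdm16, Runx3, Zbtb16 and Zfpm1 only lower ones. In this group 7 of 12 higher and 11 of 17 lower positions passed limma, and 11 and 14 when adjusted over the list alone. Nfix, of the nuclear factor I family, had both, with 6 intronic island positions at 29.9% ± 4.45 (SD, n = 3) and 49.1% ± 0.577 (SD, n = 2), and 4 others at 23.8% ± 5.30 (SD, n = 3) and 8.78% ± 0.937 (SD, n = 2).

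Other lineage markers were sparse. Granulocyte and monocyte genes had 4 higher and 1 lower clusters (adjusted p = 0.981), with the cytokine receptor gene Csf2ra at 7.41% ± 0.578 (SD, n = 3) and 21.4% ± 16.8 (SD, n = 2). The only lower position of that group was assigned to Tlr4 from 1029514 bp away. Erythroid and megakaryocyte genes had 2 higher and 1 lower clusters (adjusted p = 1.0), among them the platelet glycoprotein gene Gp1bb at 34.6% ± 3.07 (SD, n = 3) and 61.2% ± 15.8 (SD, n = 2). The red cell anion exchanger gene Slc4a1 stood at 59.6% ± 3.24 (SD, n = 3) and 42.8% ± 18.1 (SD, n = 2). Stem and progenitor surface genes had 1 position, in the promoter of the niche chemokine gene Cxcl12, at 4.02% ± 3.88 (SD, n = 3) and 14.1% ± 10.7 (SD, n = 2). Single pools moved these values. The difference was 2.12 points in Csf2ra and 15.4 in Gp1bb without G5 pool 1, and 2.53 in Cxcl12, -4.06 in Slc4a1 and -6.25 in Tlr4 without G5 pool 2. Limma passed 1 of 5 granulocyte and monocyte, 1 of 2 erythroid and 0 of 1 stem cell higher positions, and 0, 1 and 0 when adjusted over the list alone.

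Groups tied to telomeres, DNA damage and methylation also held few positions. Telomere maintenance genes had 3 genes with a position, Tert and Pinx1 higher and Terf2ip lower, in 2 higher and 1 lower clusters (Fisher's exact test, adjusted p = 1.0). All 9 higher positions passed limma, also when adjusted over the list alone. Of these, 8 were the Tert positions described above, at the locus of the engineered allele, so the count does not speak for the group. The Terf2ip position lay 204184 bp from its start site at 92.4% ± 6.83 (SD, n = 3) and 78.2% ± 30.8 (SD, n = 2), and without G5 pool 2 it was 7.63 points higher in G5. DNA damage and p53 pathway genes had 3 higher and 5 lower clusters (Fisher's exact test, adjusted p = 1.0). Within them Pmaip1, a pro-apoptotic p53 target, had 2 lower positions about 9321 bp from its start site at 69.4% ± 9.81 (SD, n = 3) and 30.4% ± 2.68 (SD, n = 2), both past limma. It also had 1 higher exonic position, at 66460932, with 10.9% ± 6.27 (SD, n = 3) and 27.4% ± 3.44 (SD, n = 2), which did not pass. Assigned to Gadd45b, a stress response gene, were 2 higher positions 22825 to 22916 bp from its start site. They stood at 89.0% ± 7.18 (SD, n = 3) and 99.0% ± 1.44 (SD, n = 2). Regulators of DNA methylation and chromatin had 2 higher and 3 lower clusters (adjusted p = 1.0). Among them were 2 higher exonic positions -8136 to -8149 bp from the start site of the histone demethylase gene Kdm6b. They stood at 21.6% ± 2.88 (SD, n = 3) and 34.8% ± 7.0 (SD, n = 2), a difference that was 8.26 points without G5 pool 2. Limma passed 1 of 4 higher and 3 of 6 lower DNA damage positions, 2 and 5 when adjusted over the list alone, and 0 of the 6 chromatin positions on either basis.

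Imprinted genes, RNA splicing factors and signalling genes were spread over both directions. Imprinted genes had 7 higher and 8 lower clusters (adjusted p = 1.0). Assigned to Plagl1 were 6 island positions at chromosome 10, 13061071 to 13061221. They lay -29567 to -29717 bp from its start site, outside annotated promoters, exons and introns. Their level was 69.9% ± 4.92 (SD, n = 3) in G0 and 93.1% ± 0.129 (SD, n = 2) in G5, and all 6 passed limma. Peg12 had 3 lower promoter positions at 25.9% ± 4.60 (SD, n = 3) and 10.1% ± 2.21 (SD, n = 2), and 1 higher promoter island position at 16.9% ± 3.75 (SD, n = 3) and 42.2% ± 27.4 (SD, n = 2). That higher position did not pass limma, and its difference was 5.91 points without G5 pool 2, against 25.3 with it. RNA splicing factors had 9 higher and 7 lower clusters (adjusted p = 1.0), and Rbfox3 held both, with 4 higher intronic positions at 22.8% ± 1.78 (SD, n = 3) and 49.5% ± 10.5 (SD, n = 2) and 2 lower ones at 84.4% ± 2.64 (SD, n = 3) and 70.0% ± 6.07 (SD, n = 2). Genes of Wnt, TGF-beta and Notch signalling had 23 higher and 20 lower clusters (adjusted p = 1.0). The ligand gene Wnt3a stood at 68.3% ± 3.81 (SD, n = 3) and 91.6% ± 1.80 (SD, n = 2) over 3 intronic positions. Assigned to Smad7, an inhibitor of TGF-beta signalling, were 2 lower shore positions -25594 to -25796 bp from its start site. They stood at 93.4% ± 1.5 (SD, n = 3) and 75.3% ± 1.42 (SD, n = 2). Limma passed 6 of 15, 4 of 11 and 10 of 30 higher positions of these 3 groups, and 7, 4 and 6 when adjusted over the list alone. It passed 3 of 10, 1 of 7 and 6 of 22 lower positions, and 5, 1 and 4 on the second basis.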

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

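The tests on limma, group overlap, levels of 20 to 80%, the 10 kb limit and the X share were chosen after the data were seen. So were the removal of distal chromosome 4, the removal of each sample in turn, and clusters as the unit for isolated positions on chromosome 4. The other alternatives were chosen before. The CpG island excess kept its direction in all 9 alternatives and its side of the threshold in 8, with 6.20 points without overlap of the groups against 10.7 in the main test, and the X chromosome deficit of higher clusters kept both in 5 of 6. Read depth per position is unknown, so no result was weighted by it. The coverage minimum of 20 reads and the read count model were not run. Unless a construction is named, the cause of a change was not tested.

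Subsets are smaller by construction. The counts of higher and lower positions were 1134 and 836 at a q-value under 0.001, 30 and 22 at 40 points or more, and 1260 and 993 at levels of 20 to 80%. The percent higher was 57.6 at the stricter q-value, 57.7 at 40 points, 57.5 on autosomes and 52.4 over clusters. Genes with only higher, only lower and both kinds of positions numbered 691, 563 and 80 at the stricter q-value, 20, 12 and 0 at 40 points, 636, 580 and 112 at levels of 20 to 80%, 396, 265 and 48 with 2 positions per gene, and 810, 656 and 129 within 10 kb. The number of gene lists past the threshold, 2 in the main test, was 1 at the stricter q-value, on autosomes and for positions without overlap, and 0 at 40 points, at levels of 20 to 80%, with genes as the unit and within 10 kb. Where these calls were lost, other than at 40 points, the homeobox excess was 10.2 to 16.8 points against 13.3 in the main test, and the myelodysplastic syndrome difference -44.0 to -23.6 points against -37.6.

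At 40 points or more the size difference turned to 16.6 points and passed (permutation test, p = 0.00278), the distal end difference rose to 33.3 points without passing, the X share turned to 4.55, and the promoter, island and gene body differences of 0.758, 14.4 and 14.4 points lost their calls, over 22 higher and 12 lower clusters. At 40 points without distal chromosome 4 the size difference was -0.770 points and the distal end difference -5.56 points, neither past the threshold, over 9 higher and 12 lower clusters. Without distal chromosome 4 the size difference was -0.454 points and passed (permutation test, p = 0.0377). The promoter difference was -0.496 points at the stricter q-value, -0.580 without overlap, 1.99 at levels of 20 to 80%, 0.546 over single positions and 2.23 with promoters from the RefSeq annotation, none past the threshold. The gene body difference was 3.91 points without overlap and 3.65 at levels of 20 to 80%. The distal end difference, 0.254 points in the main test, was 2.20 points at the stricter q-value, -0.842 points over single positions and -0.0268 at 10 Mb.

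Without each sample in turn, positions whose groups did not overlap numbered 2333 to 2463 higher and 1780 to 1953 lower, and limma called 0 to 844 higher and 0 to 708 lower. The overlap counts cannot fall below the 2276 and 1737 of all 5 samples, since groups that are apart stay apart when a sample is removed. They are therefore no check of stability. In limma with 1 G5 pool left out, the lone pool was assumed to vary like the G0 pools. Samples that share a replicate number showed little common deviation (correlation of deviations 0.0124 and 0.0476 over 2 pairs). The deviations of the 2 G5 pools mirror each other, so the 2 pairs are not independent checks and cannot exclude a shared batch. With the replicate block limma called 0 higher and 0 lower positions, against 868 and 683, and 835 and 691 passed an unadjusted p of 0.05.

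Some results on single lists and genes turned in direction without being past a threshold. At levels of 20 to 80% the excess of higher clusters was -52.8 points for granulocyte and monocyte genes (0 higher and 1 lower). It was -2.80 for erythroid genes (1 and 1), 47.2 for chromatin regulators (1 and 0) and 7.25 for imprinted genes (6 and 4). These values rest on too few clusters to show a direction. The excess was -3.58 for erythroid genes without overlap (1 and 1), 4.18 for imprinted genes over single positions and -0.648 for signalling genes with genes as the unit. Without each sample in turn the 3110070M22Rik difference ranged from -69.5 to 4.46 points and the Terf2ip difference from -35.9 to 7.63 points, the positive values being those without G5 pool 2.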

Other observations

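Several loci outside the named genes stood apart, and were chosen after their values were seen. Positions of the ribosomal RNA repeat gene Rn45s on chromosome 17 were listed in both directions, with 6 higher positions at 31.1% ± 13.1 (SD, n = 3) in G0 and 61.7% ± 3.40 (SD, n = 2) in G5 and 2 lower ones at 47.8% ± 15.7 (SD, n = 3) and 35.5% ± 10.9 (SD, n = 2). The lower difference of -12.3 points was -3.38 without G0 pool 2 and -4.64 without G5 pool 1. This gene is a repeat, so reads of its many copies share a position. Near the pseudoautosomal end of X, 3 positions of Asmt, which encodes the last enzyme of melatonin synthesis, stood at 56.8% ± 7.92 (SD, n = 3) and 98.2% ± 0.828 (SD, n = 2). The only Y-linked position, assigned to Erdr1, stood at 5.19% ± 7.14 (SD, n = 3) and 58.2% ± 42.4 (SD, n = 2). The G5 pools stood at 28.2% and 88.1%, so the difference was 82.9 points without G5 pool 1 and 23.0 without G5 pool 2. Toward lower methylation, 4 positions of 4930405P13Rik on chromosome 11 (88896150 to 88896183) stood at 92.9% ± 4.94 (SD, n = 3) and 40.5% ± 23.9 (SD, n = 2). Assigned to Cerk, a ceramide kinase gene, were 4 positions at chromosome 15, 86194823 to 86194856. They stood at 91.6% ± 1.81 (SD, n = 3) and 45.2% ± 9.49 (SD, n = 2).

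Of 8 gene families set by symbol after the data were seen, none differed in direction from other clusters (Fisher's exact test, smallest adjusted p = 0.844). Potassium channel genes had 22 higher and 17 lower clusters, solute carriers 37 and 34, microRNA genes 33 and 24, Zfp zinc fingers 28 and 19, protocadherins 7 and 4, and Hox genes 8 and 7. Olfactory receptor genes had 4 and 9, and vomeronasal receptor genes 5 and 9.

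In the patterns below, the tests of regional change on chromosome 4 and of uneven read sampling were set before their results were seen, and the other 5 tests after. Higher methylation of Tert exon 1 in G5 coincides with the genotype, since G0 mice carry 1 TERT-ER allele and G5 mice 2. A base variant at a measured cytosine would change 1 CpG, and 7 CpGs within 68 bp moved together. A gain across the linked region would raise its neighbours, and 52.4% of the other listed positions within 5 Mb (11 of 21) were higher, 0 of them by 40 points. The dose of an allele methylated on its own copies and a methylation change at Tert with short telomeres cannot be told apart, since every pool of a group has 1 genotype. The G5 to G0 ratio was 2.04, with single pools giving 1.67 to 2.48, and does not separate these 2 explanations.

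The 11 positions past 60 points on distal chromosome 4 had medians of 0% in G0 pools 1 and 3, 40.5% in G0 pool 2 and 97.6% and 96.9% in the G5 pools. A regional change of methylation would raise the other listed positions of the interval, and 48.5% of them (32 of 66) were higher. A strain variant that removes single CpGs in the G0 pools, with both alleles in G0 pool 2, is an explanation that stays open in mice of mainly C57BL/6 background. The Acap3 position, at 9.52% and 34.4% in G0 pools 1 and 3, would need both alleles in all 3 G0 pools. A variant predicts isolated positions, and 18.2% (2 of 11) had another listed CpG within 100 bp, against 73.2% (30 of 41) of other positions past 40 points (Fisher's exact test, p = 0.00148). Neighbouring positions count each other in that test. Over clusters the shares were 2 of 11 and 12 of 23 (52.2%; Fisher's exact test, p = 0.0764), which does not settle it. No genotypes were used here, so a strain variant and a change of methylation at these CpGs cannot be told apart.

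X-linked promoter islands were partly methylated and over-represented among lower positions. A different share of female mice in the pools would move them one way, and 35.1% (78 of 222) went against the majority. Such a share alone would not give those 78 positions, but the excess of lower positions could still come from it. Positions listed for a difference in either direction cannot decide how much of the excess it accounts for. Uneven sampling of reads at partly methylated CpGs would make the groups overlap more on X, and the share without overlap was 1.5 points above that of autosomal positions of like G0 level (90.2% of 347 against 88.7% of 1372, Fisher's exact test, p = 0.501). All these positions were listed for a group difference, which narrows what that comparison can show. The sex of the pooled mice is not given in the labels, and an effect of the G5 genotype on X stays open as untested.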
